A study of Mus musculus with 6 samples.

How the data were processed

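Mature B cells from mouse spleen were activated, infected with retrovirus by the authors, returned to mitogen for 36 hours, washed, cultured for 24 hours without mitogen and sorted for green fluorescence. RNA was extracted with TRIzol, labelled with biotin and hybridised to Affymetrix mouse ST 1.0 arrays, 1 array per sample. The 6 arrays were grouped by their labels as EV, IKK_K171E and MYD88_L265P, with 2 arrays each, and the labels describe the arrays of a group as biological replicates. Replicates are numbered 1 and 2 after their descriptions, and the titles number replicate 2 as 3 in every group, and replicate 1 as 2 in EV and as 1 in the others.

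The deposited values are log2 expression per feature, processed by the authors, whose notes name oligo and limma without versions. The method of background correction, normalization and summarization is not given in the sources used here, and neither is a genome build. The deposited table holds 24743 features, with values from 2.55 to 14.5 and array medians from 8.03 to 8.13. It holds no detection p-values, so low signal was not separated from background. No value was transformed, scaled or filtered before the fit.

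Features were tested when the platform annotation gave exactly 1 gene symbol, which left 21542 features of 19818 genes. Of the others, 1522 had several symbols and 1679 had none. Entrez identifiers of 21472 features were found in the RefSeq table, and 0 symbols changed. Among the tested features, 112 carry values identical to those of another feature of the same gene, in 46 sets. Over 1 feature was tested for 926 genes, so counts of features can exceed counts of genes. Genes numbered 1838 higher and 1514 lower in MYD88_L265P than in EV, and 198 and 89 in IKK_K171E than in EV. They numbered 185 higher and 182 lower in MYD88_L265P than in IKK_K171E.

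Group means were fitted to all 6 arrays in 1 linear model with limma 3.58.1 in R 4.3.3, followed by contrasts and empirical Bayes moderation (3 residual and 4.17 prior degrees of freedom). P-values were two-sided and adjusted by Benjamini-Hochberg over the features of a comparison, and a feature was called at an adjusted p below 0.05. The 2 comparisons with EV share its arrays, and the correlation and covariance of their log2 fold changes were set beside 100 simulated data sets with no effect. Noise in these data sets was independent between genes. The other numbers given in the titles and descriptions were not used to pair arrays in the reported fit.

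For 31 lists of genes (746 genes, 686 measured) each gene was represented by its brightest feature. Lists were tested with camera at a preset correlation of 0.01, with Benjamini-Hochberg over the 31 lists, and again with an estimated correlation and with fry (statmod 1.5.0 was installed). Members were also counted after adjustment over the list alone. The lists covered signalling, B cell, cell cycle, metabolic and stress programmes, markers of other cell types, and marginal zone and B1 cells. The named genes were the 8 largest changes in each direction with separated arrays, the 3 largest called members of each called list in its direction, the largest called member of each other list, and the genes nearest to the transduced ones. The groups, tests, lists and this naming rule were chosen before the data were examined.

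The procedure was tested on simulated data of 21542 features, in which 67 features were changed 1.5-fold, 67 2-fold and 66 4-fold in each comparison. At 2-fold, 80.6%, 85.1% and 97.0% of changed features were called in MYD88_L265P against EV, IKK_K171E against EV and MYD88_L265P against IKK_K171E. At 1.5-fold the shares were 29.9%, 29.9% and 28.4%, at 4-fold 100%, and 3, 8 and 7 unchanged features were called. The 3 runs used the same means and variance model, with noise independent between genes. Their shares differ by the random draw and do not rank the comparisons.

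Alternatives covered the replicate numbers as a block, quantile normalization, a common median, the variance model, array weights, a filter on low signal, the features and arrays included, a 2-fold threshold, the set tests, and each array left out in turn. Quantile normalization and the common median were added for the gene lists after the data were seen. Splits of the samples were not counted, since groups of 2 are below the size for that check.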

Results

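Gene expression was measured in mature B cells from mouse spleen that had been activated, transduced with a retrovirus carrying a green fluorescent protein marker, and sorted for that marker. The cells carried the empty vector (EV), an IKK construct with the K171E substitution (IKK_K171E) or MYD88 with the L265P substitution (MYD88_L265P), a change found in human B cell lymphomas. MYD88 is the adaptor that links Toll-like and interleukin-1 receptors to NF-kB, and the IKK kinases act on the inhibitors of NF-kB. After transduction the cells spent 36 hours with mitogen and then 24 hours without it before sorting, so that the arrays recorded expression after the stimulus was removed. Each of the 3 groups had 2 Affymetrix mouse ST 1.0 arrays, described as biological replicates. P-values set the difference between group means against the spread between replicate arrays, pooled over all 3 groups and moderated. Replicate arrays correlated across features at 0.989 in EV, 0.992 in IKK_K171E and 0.995 in MYD88_L265P. Some arrays of different groups were as close as the EV replicates. Pairs between groups ran from 0.967 (EV replicate 2 and MYD88_L265P replicate 2) to 0.990 (IKK_K171E replicate 1 and MYD88_L265P replicate 1). The small number of arrays limits the precision. The first principal component held 60.4% of the variance and ran from EV (-20.5 and -33.0) through IKK_K171E (7.80 and -10.3) to MYD88_L265P (27.5 and 28.5). The second held 17.2% and had its lowest scores in IKK_K171E (-19.7 and -14.5). Of 21542 features with exactly 1 gene symbol, limma with Benjamini-Hochberg adjustment found 3586 that differed between MYD88_L265P and EV, 295 between IKK_K171E and EV, and 377 between MYD88_L265P and IKK_K171E.

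The transduced genes were examined first. Myd88 had a log2 signal of 12.28 (SD 0.04, n = 2) in MYD88_L265P, 9.32 (SD 0.03, n = 2) in EV and 9.28 (SD 0.21, n = 2) in IKK_K171E. It rose by 2.96 over EV (SE 0.11, limma adjusted p = 2.81e-04) and by 2.99 over IKK_K171E (adjusted p = 2.45e-04). Ikbkb, which encodes the catalytic IKK beta subunit, read 11.35 and 10.68 in IKK_K171E replicates 1 and 2, 9.98 and 10.22 in EV, and 9.69 and 9.68 in MYD88_L265P. Its log2 fold change in IKK_K171E over EV was 0.91 (SE 0.21, adjusted p = 0.0848), which missed the threshold, and against MYD88_L265P the difference passed it (MYD88_L265P minus IKK_K171E -1.33, SE 0.21, adjusted p = 0.0305). Ikbkg, the regulatory subunit, had log2 fold changes of -0.26 and -0.18 against EV and passed in no comparison. The construct is labelled IKK without a subunit, and Chuk, the gene of IKK alpha, had no feature among those tested.

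**Figure D1:**
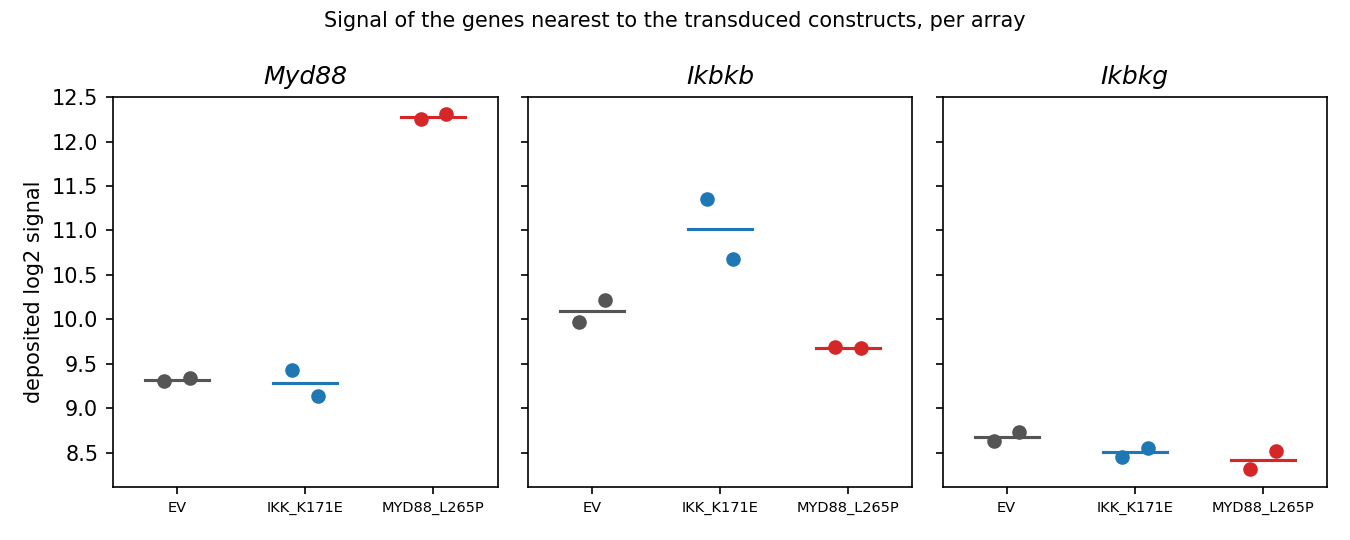
Deposited log2 signal (vertical axis) of Myd88, Ikbkb and Ikbkg in the 3 groups (horizontal axis). Each point is 1 array, replicate 1 to the left of replicate 2, and each line is the mean of 2 arrays. Both MYD88_L265P arrays had Myd88 at 12.3, and the IKK_K171E arrays had Ikbkb at 11.35 and 10.68.

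The first comparison asked what MYD88_L265P changed relative to the empty vector. Many genes of antibody-secreting cells, DNA replication, ribosome assembly and the unfolded protein response rose, and many genes of the mature B cell surface, antigen presentation and B cell receptor signalling fell. Prdm1, the transcription factor that drives plasma cell differentiation, rose by 2.47 on the log2 scale (SE 0.22), from 8.02 (SD 0.15, n = 2) to 10.50 (SD 0.23, n = 2), and Jchain, which joins IgM and IgA polymers, rose by 2.22 (SE 0.60). Fcer2a, the low-affinity IgE receptor CD23 of follicular B cells, fell by 1.81 (SE 0.41), and Fcmr, the IgM Fc receptor, fell by 1.97 (SE 0.20). In all, 2007 features were higher and 1579 lower, of which 387 and 91 changed by at least 2-fold.

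The largest increases in MYD88_L265P over EV were in Mybl1 (3.51, SE 0.37), a MYB family transcription factor of germinal centre B cells, and in Tnip3 (3.25, SE 0.19), which encodes an A20-binding inhibitor of NF-kB. Tmed6 rose by 3.18, Pcbd1 by 3.16, Nqo1, a quinone oxidoreductase, by 3.05, and Depdc7 by 2.69. Il6 rose by 3.07 (SE 0.50, adjusted p = 0.0122), from EV arrays that themselves stood at 7.19 and 5.39. The largest decreases were in Xkrx (-2.29, SE 0.24), Fcmr, Ephx1 (-1.90), the chemokine receptor genes Ccr6 (-1.84) and Ccr1 (-1.75), Fcer2a, Adgre1 (-1.78) and Zfp318 (-1.77), a regulator of IgD expression. Over the 62 genes named for this comparison the SE ran from 0.0853 to 0.602, and the 60 that passed had limma adjusted p-values from 2.81e-04 to 0.0484.

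Among 31 lists of genes fixed before the data were examined, camera placed 7 higher and 5 lower in MYD88_L265P than in EV. The list of G1/S and DNA replication genes had 26 of 42 members higher and 0 lower (36 higher and 1 lower adjusted over the list alone), with Ccne2, a cyclin of S phase entry, at 1.78, Tyms, which makes thymidylate, at 1.47 and E2f3 at 1.37. Of the MYC and ribosome biogenesis list, 20 of 33 members rose and 0 fell (32 and 0 adjusted over the list alone), led by the spermidine synthase gene Srm (1.97), Rrs1 (1.72) and the nucleolar gene Nop58 (1.51). The preset camera gave adjusted p = 4.43e-18 for the replication list (adjusted p = 0.412 with an estimated correlation) and 3.45e-18 for the ribosome list (adjusted p = 0.396 with an estimated correlation). Of the unfolded protein and integrated stress response list, 20 of 30 members rose and 0 fell (23 and 1 adjusted over the list alone, camera adjusted p = 9.15e-15, adjusted p = 0.396 with an estimated correlation). Its members included Asns, asparagine synthetase, at 2.34, Creld2 at 1.49 and the disulfide isomerase gene Pdia6 at 1.48. The plasma cell programme had 13 of 26 members higher and 3 lower (16 and 3 adjusted over the list alone, camera adjusted p = 2.81e-07, adjusted p = 0.396 with an estimated correlation). The cholesterol list had 9 of 20 higher and 0 lower (12 and 1 adjusted over the list alone), with Idi1 at 2.02, Hsd17b7 at 1.11 and Sqle, squalene epoxidase, at 1.01, and camera gave adjusted p = 2.42e-06 (adjusted p = 0.396 with an estimated correlation).

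Mitotic and glycolytic genes stood apart from this picture. The G2/M and mitosis list had a median log2 fold change of 0.86 in MYD88_L265P over EV, which was 1.42 without EV replicate 1 and 0.31 without EV replicate 2. Cdk1 (1.18, SE 0.32, EV SD 0.78) and Aurka (0.89, SE 0.23, EV SD 0.53) of its 39 members passed, and 0 passed adjusted over the list alone. Camera gave adjusted p = 4.85e-12 for this list and adjusted p = 0.556 with an estimated correlation. Of 20 glycolysis genes, 5 rose and 2 fell (also 5 and 2 adjusted over the list alone), among them hexokinase 2, Hk2, at 1.23, the monocarboxylate transporter gene Slc16a1 at 1.19 and Pgam1 at 0.63. The camera adjusted p was 0.0247 for glycolysis (adjusted p = 0.556 with an estimated correlation), and the call ended without EV replicate 2 (adjusted p = 0.113) and without MYD88_L265P replicate 1 (adjusted p = 0.0521). It also ended under quantile normalization (median 0.082, adjusted p = 0.131) and with the features of lowest signal left out (adjusted p = 0.153).

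The mature B cell identity list had 16 of 28 members lower in MYD88_L265P than in EV and 1 higher (21 and 2 adjusted over the list alone), including Fcrl1 at -1.44 beside Fcmr and Fcer2a. The camera adjusted p was 1.62e-05 (adjusted p = 0.396 with an estimated correlation). Of 16 MHC class II presentation genes, 8 fell and 0 rose (12 and 0 adjusted over the list alone, camera adjusted p = 4.45e-04, adjusted p = 0.396 with an estimated correlation). H2-Oa and H2-Ob, the subunits of the peptide-loading modulator DO, fell by 1.52 and 1.27, and H2-DMa of the loading factor DM fell by 1.07. In the B cell receptor list 11 of 26 members fell and 0 rose (15 and 0 adjusted over the list alone, camera adjusted p = 1.01e-04, adjusted p = 0.396 with an estimated correlation), with the inhibitory receptor gene Cd22 at -0.78, the phosphatase gene Inpp5d at -0.69 and the receptor subunit gene Cd79b at -0.67. The FOXO and quiescence list had 11 of 24 lower and 0 higher (13 and 0 adjusted over the list alone, camera adjusted p = 1.99e-04, adjusted p = 0.396 with an estimated correlation), led by Txnip (-1.38), a brake on glucose uptake, Sesn1 (-0.83) and the antiproliferative gene Btg1 (-0.83). The T cell list had 4 of 19 members lower (8 adjusted over the list alone), including Cd2 (-0.69), Cd3g (-0.67) and Cd3e (-0.47), and its camera adjusted p of 0.00719 (adjusted p = 0.516 with an estimated correlation) rose to 0.0677 without MYD88_L265P replicate 2.

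NF-kB genes did not pass as a list in MYD88_L265P against EV: 5 of 32 were higher and 8 lower (5 and 11 adjusted over the list alone). Camera gave adjusted p = 0.957, with a direction opposite to the median of -0.10. Cytokine and chemokine genes split into 5 higher and 5 lower of 42, and STAT3 and cytokine signalling genes into 5 higher and 3 lower of 24. Migration receptor genes had 4 higher and 8 lower of 24, and the list passed as lower under quantile normalization (adjusted p = 0.00279) and with a common median (0.0296). Immediate early and MAPK feedback genes had 4 higher and 6 lower of 30, and the phosphatase gene Dusp10 rose by 1.02. MHC class I genes had 3 higher and 7 lower of 16, and Calr, also a chaperone of the endoplasmic reticulum, rose by 0.91. B cell activation genes had 1 higher and 10 lower of 27 (camera adjusted p = 0.0576), a list that passed without EV replicate 1 (adjusted p = 0.0205), without EV replicate 2 (0.0299) and without MYD88_L265P replicate 1 (0.00711). It also passed under quantile normalization (6.63e-04), with a common median (0.0126) and with the features of lowest signal left out (0.0217). Pim2, a survival kinase gene, rose by 1.53 in a list of survival genes with 3 higher and 1 lower of 11, a list that passed without MYD88_L265P replicate 2 (adjusted p = 0.0402) and with the mean of the features of a gene (0.0335). The cytochrome c gene Cycs rose by 1.37 in a list of apoptosis genes with 1 higher and 2 lower of 18. Ly96, the partner of TLR4, rose by 1.22 among 30 Toll-like receptor pathway genes with 2 higher and 4 lower. The interferon list had 2 of 29 members lower, Zbp1 at -0.91 among them, and passed as lower without MYD88_L265P replicate 1 (adjusted p = 0.00486). The p53 list had 1 higher and 2 lower of 22, with Rps27l at 1.44, and the germinal centre list 1 higher and 5 lower of 19. The marginal zone and B1 list had 2 higher and 3 lower of 17, with Cr2, complement receptor 2, at -1.31. Of all tested features 16.6% were called in this comparison. Among markers of other cell types, NK cells had 2 higher and 3 lower of 14 (Klrd1 -1.16), and dendritic cells 1 higher and 2 lower of 15 (Ccr9 1.49). Ly6g (-0.49) was the 1 of 18 neutrophil genes called and Adgre1 the 1 of 20 monocyte and macrophage genes. Tfrc, the transferrin receptor gene of dividing cells in general, was the 1 of 10 erythroid genes (1.68). The count for MYD88_L265P against EV was 1320 without EV replicate 2, 415 without MYD88_L265P replicate 1 and 191 without MYD88_L265P replicate 2, against 3586 with all arrays. Of the 62 named genes 9, 28 and 35 lost the call. The median feature lay at -0.11, and shifting all arrays to a common median moved this to -0.03 and the share of higher calls from 56.0% to 77.4%.

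**Figure D2:**
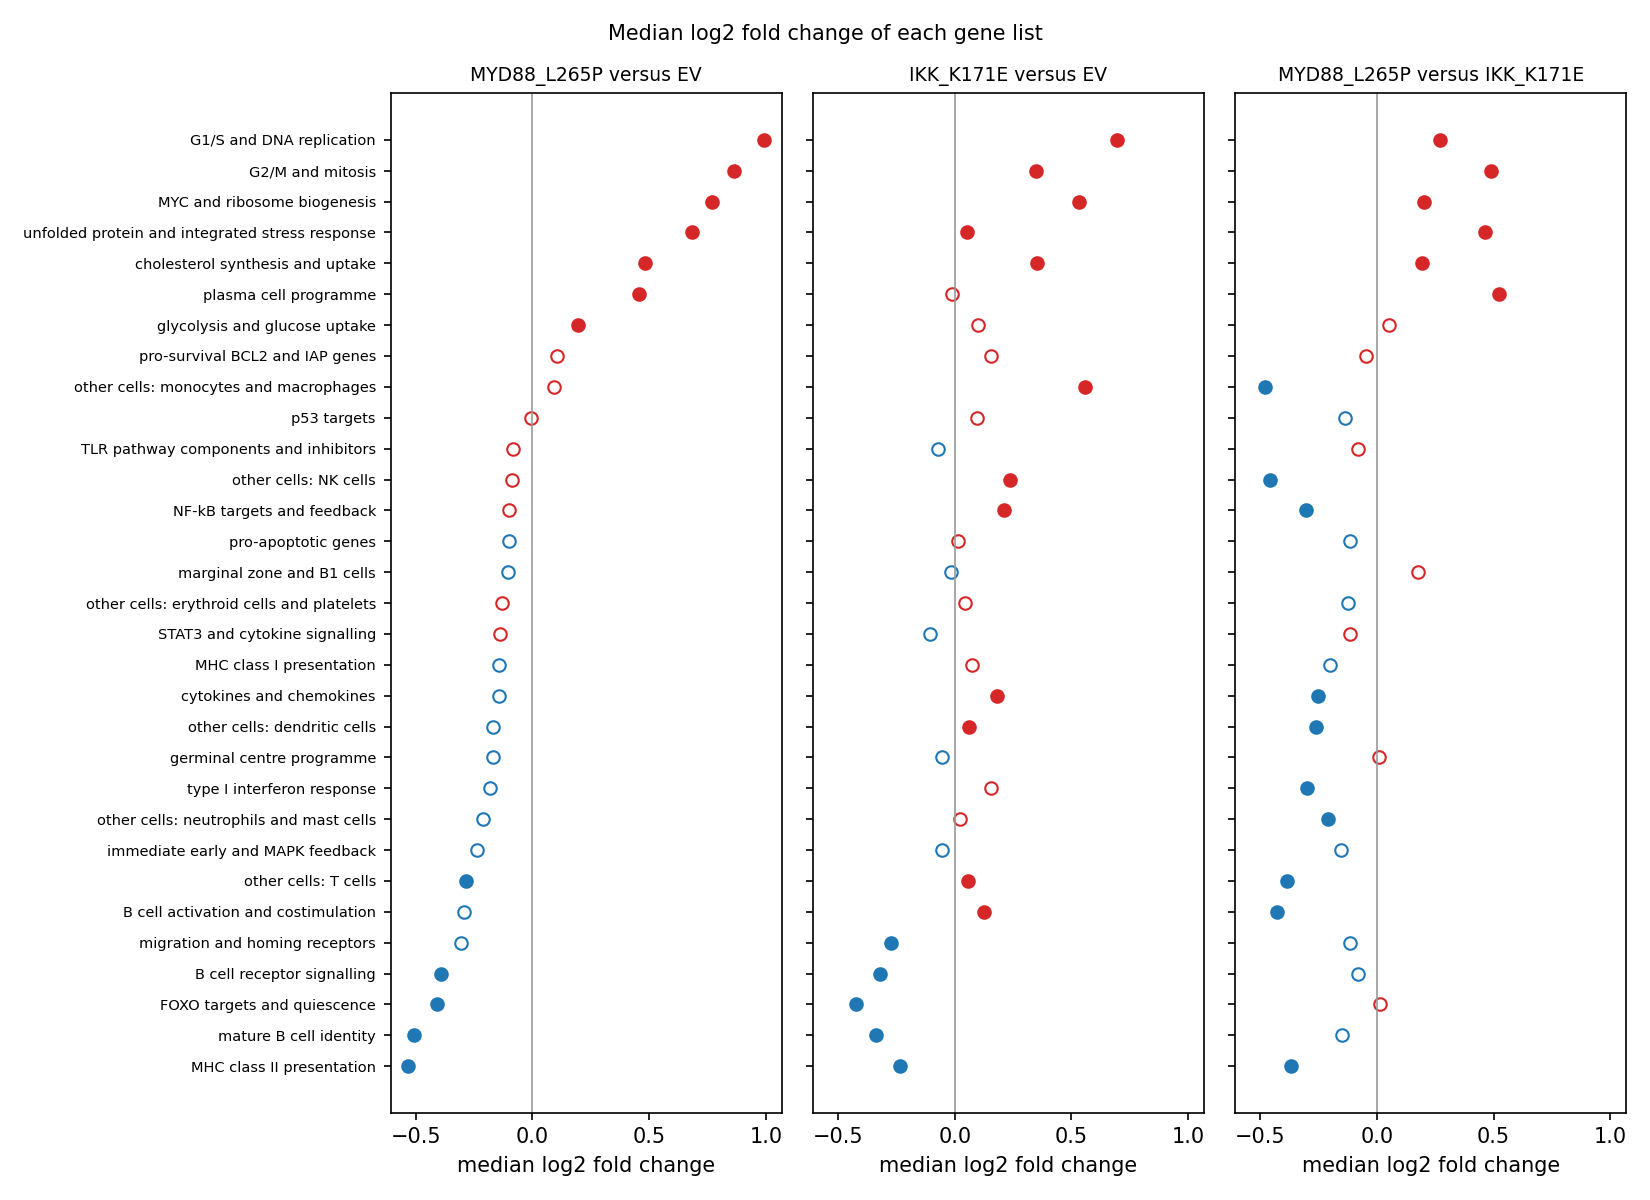
Median log2 fold change (horizontal axis) of each of the 31 gene lists (vertical axis) in the 3 comparisons. Filled points are lists called by camera with the preset correlation, open points are lists not called, red is a camera direction up and blue down. The G1/S and DNA replication list lay highest in MYD88_L265P versus EV at 0.99, and the monocyte and macrophage list lay at 0.56 in IKK_K171E versus EV.

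The next comparison asked what IKK_K171E changed relative to the same empty vector arrays. The chemokine genes Ccl22 and Cxcl10, the cytokine gene Il1b and the receptor gene Cd40 rose, together with Ccne2 and Rrs1, and Txnip and Bach2 fell. Most members of the lists that hold these genes did not pass. Ccl22, a chemokine gene of activated B and dendritic cells, rose by 2.18 (SE 0.37), from 10.30 (SD 0.29, n = 2) to 12.48 (SD 0.43, n = 2). Cxcl10 rose by 1.61 (SE 0.14), Il1b by 1.52 (SE 0.13) and Cd40 by 1.06 (SE 0.13). In all, 206 features were higher and 89 lower, of which 80 and 8 changed by at least 2-fold.

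The largest increases in IKK_K171E over EV were in Clec4a3 (2.37, SE 0.22), Ifi205 (2.31), Fyb (2.18), Ccl22, Lcp2 (2.07), Dctd (1.98), Clec4n (1.93), which encodes the C-type lectin dectin-2, and Lilr4b (1.86). Fyb and Lcp2 encode adaptors of immune receptor signalling. The largest decreases were in Tgfb3 (-1.33, SE 0.21), Satb1 (-1.24), a chromatin organiser of lymphocytes, Cpm (-1.24), Tcp11l2 (-1.19), Adgre1 (-1.17), Sorl1 (-1.08), Nod1 (-1.07) and Pold4 (-1.03). Over the 53 genes named here the SE ran from 0.0826 to 0.374, and the 50 that passed had limma adjusted p-values from 0.00612 to 0.0492. Markers of monocytes and macrophages moved alongside: the list had a median log2 fold change of 0.56 in IKK_K171E over EV, with 1 of 20 members higher (Csf1r, the CSF1 receptor gene, 1.22) and 1 lower (Adgre1), and 13 higher and 1 lower adjusted over the list alone. The camera adjusted p was 6.41e-08 for it and adjusted p = 0.290 with an estimated correlation.

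Camera placed 12 lists higher and 5 lower in IKK_K171E than in EV. The NF-kB list had 2 of 32 members higher and 0 lower (6 and 0 adjusted over the list alone), Ccl22 and Tnfaip3 (1.02), the gene of the feedback inhibitor A20, and the cytokine list had 6 of 42 higher and 0 lower (11 and 1 adjusted over the list alone). Both had a camera adjusted p of 2.89e-05 (adjusted p = 0.290 with an estimated correlation), beside the monocyte and macrophage median of 0.56. Fry called neither list (adjusted p = 0.0959 and 0.0742). The NF-kB median of 0.21 was 0.13 without IKK_K171E replicate 1, and the cytokine median of 0.18 was 0.075 without EV replicate 2. In the B cell activation list 3 of 27 members rose, also 3 adjusted over the list alone, with Cd80, a ligand of CD28, at 0.67 and the death receptor gene Fas at 0.58 beside Cd40 (camera adjusted p = 0.0109, adjusted p = 0.407 with an estimated correlation). This call ended with the features of lowest signal left out (adjusted p = 0.0544). The MYC and ribosome list had 3 of 33 members higher (19 adjusted over the list alone), Nop58 at 1.23, Rrs1 at 1.21 and Gnl3 at 1.12, and the G1/S list had 2 of 42 higher (23 adjusted over the list alone), Ccne2 at 1.42 and E2f3 at 1.03. Their camera adjusted p-values were 1.97e-18 (adjusted p = 0.317 with an estimated correlation) and 2.67e-16 (adjusted p = 0.385 with an estimated correlation). Fry did not call them (adjusted p = 0.113 and 0.168). The MYC median of 0.53 was 0.29 and 0.81 without IKK_K171E replicates 1 and 2. The G1/S median of 0.69 was 0.39 without EV replicate 2. Cholesterol genes had 2 of 20 higher (9 higher and 1 lower adjusted over the list alone), Idi1 at 1.71 and Cyp51 at 0.69. Camera gave adjusted p = 8.57e-04 (adjusted p = 0.407 with an estimated correlation). The cholesterol median of 0.35 was 0.19 without EV replicate 2. Of the G2/M list 0 of 39 members passed, also 0 adjusted over the list alone. Its median of 0.35 (camera adjusted p = 1.30e-04, adjusted p = 0.606 with an estimated correlation) became 0.92 without EV replicate 1 and -0.17 without EV replicate 2, where camera called it lower (adjusted p = 1.01e-04), and the call ended without IKK_K171E replicate 1 (adjusted p = 0.0533).

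Camera also called the stress response, dendritic cell, NK cell and T cell lists higher in IKK_K171E over EV. Of all tested features 1.37% were called in this comparison. Slc7a11, the cystine transporter gene, was the 1 of 30 stress response genes that rose (1.20), with 3 higher adjusted over the list alone and camera adjusted p = 0.00967 (adjusted p = 0.463 with an estimated correlation), a call that ended without EV replicate 1 (0.217) and without IKK_K171E replicate 1 (0.301). Of the dendritic cell list 3 of 15 rose (4 adjusted over the list alone): Flt3 at 0.75, Clec10a at 0.69 and the integrin gene Itgax at 0.68 (camera adjusted p = 0.00758, adjusted p = 0.290 with an estimated correlation). Its median of 0.06 became 0.17 and 0.12 without EV replicates 1 and 2, and 0.03 and 0.14 without IKK_K171E replicates 1 and 2. Fcer1g, an Fc receptor signalling chain of many myeloid cells, was the 1 of 14 NK cell genes that rose (2.82-fold), with 6 adjusted over the list alone and camera adjusted p = 3.13e-04 (adjusted p = 0.317 with an estimated correlation). The T cell list had 0 of 19 called, also 0 adjusted over the list alone, a median of 0.06 and camera adjusted p = 0.0354 (adjusted p = 0.463 with an estimated correlation), and the call ended without EV replicate 1 (0.268), without IKK_K171E replicate 1 (0.259) and with the features of lowest signal left out (0.137). The T cell median was 0.19 without EV replicate 2 and 0.15 without IKK_K171E replicate 2.

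Mature B cell identity genes had 5 of 28 members lower and 0 higher in IKK_K171E than in EV (12 and 0 adjusted over the list alone), among them the transcription factor gene Bach2 (-0.90), Fcrla (-0.85) and Cd72 (-0.69). The camera adjusted p was 6.35e-09 (adjusted p = 0.290 with an estimated correlation). Of 24 FOXO and quiescence genes 5 fell and 0 rose (14 and 0 adjusted over the list alone), led by Txnip (-0.99), the apoptosis activator gene Bcl2l11 (-0.82) and Ypel3 (-0.80). Camera gave adjusted p = 6.50e-11 (adjusted p = 0.290 with an estimated correlation). Cd22 (-0.64) was the 1 of 26 B cell receptor genes that fell, with 14 adjusted over the list alone (camera adjusted p = 3.47e-07, adjusted p = 0.290 with an estimated correlation). Ccr7 (-0.63), the receptor gene for homing to lymph node T zones, was the 1 of 24 migration genes that fell, with 4 adjusted over the list alone (camera adjusted p = 0.00513, adjusted p = 0.290 with an estimated correlation). MHC class II genes had 0 of 16 called and 1 lower adjusted over the list alone (camera adjusted p = 0.0169, adjusted p = 0.407 with an estimated correlation), and the call ended without EV replicate 2 (0.278) and without IKK_K171E replicate 2 (0.0563).

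Lists that camera did not call in IKK_K171E over EV included the plasma cell programme (0 of 26 called), STAT3 and cytokine signalling (0 of 24), MHC class I (0 of 16), survival genes (0 of 11), the interferon response (0 of 29) and neutrophils (0 of 18). The interferon list, with a median of 0.15 and adjusted p = 0.0513, passed as higher without EV replicate 1 (adjusted p = 0.00864), without IKK_K171E replicate 2 (0.00129), without either MYD88_L265P array (0.0137) and with a variance trend (0.0434). The STAT3 list passed as lower without EV replicate 2 (0.00165) and without IKK_K171E replicate 1 (0.0475), and the neutrophil list as higher without IKK_K171E replicate 1 (0.0268) and under quantile normalization (0.0478). Without EV replicate 2 the germinal centre list passed as lower (0.0418) and the p53 list as higher (0.0452). MHC class I passed as higher without EV replicate 1 (0.0481) and glycolysis without IKK_K171E replicate 2 (0.00117). Irf8 fell by 0.84 among 19 germinal centre genes with 1 higher and 2 lower, and Aldoc fell by 0.63 as the 1 of 20 glycolysis genes called. Plac8 fell by 0.70 as the 1 of 17 marginal zone genes, and Spred1 rose by 1.33 as the 1 of 30 MAPK feedback genes. Cycs rose by 0.85 among 18 apoptosis genes with 3 higher and 1 lower, Ly96 by 1.33 among 30 Toll-like receptor genes, Tfrc by 1.28 among 10 erythroid genes and Fas among 22 p53 genes. The count of 295 rested on single arrays: limma called 0 features without IKK_K171E replicate 1 (2355 at an unadjusted p under 0.05), 139 without EV replicate 2, 506 without EV replicate 1, 490 without IKK_K171E replicate 2, and 51 without either MYD88_L265P array. Of the 53 named genes, 50 lost the call without IKK_K171E replicate 1. Fitting only the 4 arrays of the compared groups gave the same 51 by construction, since a lone MYD88_L265P array adds nothing to the estimated spread. Including every row of the value table gave 131 calls.

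MYD88_L265P and IKK_K171E were then compared with each other, which is the direct test of any difference between them. Prdm1, Xbp1, Atf3 and Il10 were higher in MYD88_L265P, while Ccl22, Cxcl10, the lymphotoxin genes Lta and Ltb, and Fas were higher in IKK_K171E. Prdm1 was higher in MYD88_L265P by 2.19 (SE 0.22) and Il10, an anti-inflammatory cytokine gene, by 2.03 (SE 0.14), from 6.75 (SD 0.23, n = 2) to 8.78 (SD 0.04, n = 2). Ccl22 was lower in MYD88_L265P by 3.24 on the log2 scale (log2 fold change -3.24, SE 0.37), and Fcer2a differed by -2.89 (SE 0.41). In all, 188 features were higher in MYD88_L265P and 189 lower, of which 65 and 53 differed by at least 2-fold.

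Beyond Myd88, the largest differences in favour of MYD88_L265P were in Tmed6 (3.54, SE 0.13), Pcbd1 (3.11), Mybl1 (2.95), Nqo1 (2.70), Tnip3 (2.51), Rnd3 (2.46), a small GTPase gene, and Map2 (2.37). In favour of IKK_K171E they were in Ccl22, Fcer2a, Lcp2 (-2.08), Cd96 (-1.77), Fscn1 (-1.66), the actin-bundling fascin gene, Flt3 (-1.63), Tmem176b (-1.62) and Adgre4 (-1.60). The SE ran from 0.0826 to 0.408 over the 45 genes named for this comparison, and the 44 that passed had limma adjusted p-values from 2.45e-04 to 0.0484.

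Camera placed 6 lists higher and 10 lower in MYD88_L265P than in IKK_K171E. The plasma cell programme had 9 of 26 members higher and 0 lower (17 and 1 adjusted over the list alone), with Pon3 at 1.28 and Xbp1, the transcription factor gene of the secretory apparatus, at 1.20 beside Prdm1 (camera adjusted p = 3.99e-10, adjusted p = 0.312 with an estimated correlation). The stress response list had 10 of 30 higher and 0 lower (21 and 0 adjusted over the list alone), with Atf3 at 1.08 and Creld2 at 1.02 beside Xbp1 (camera adjusted p = 4.37e-17, adjusted p = 0.312 with an estimated correlation). Hsd17b7 (0.72) was the 1 of 20 cholesterol genes called, also 1 adjusted over the list alone (camera adjusted p = 3.13e-05, adjusted p = 0.404 with an estimated correlation). Of the G1/S, G2/M and MYC lists 0 members passed, and 0, 0 and 1 were higher adjusted over the list alone. Their medians were 0.27, 0.49 and 0.20, with camera adjusted p-values of 6.33e-07, 1.29e-08 and 6.61e-06 (each adjusted p = 0.539 with an estimated correlation), and the MYC list lost its call without IKK_K171E replicate 2 (median -0.05, adjusted p = 0.967). Without IKK_K171E replicate 1 the MYC median was 0.45 and the G1/S median 0.44, and without replicate 2 the G1/S median was 0.06.

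The NF-kB list had 9 of 32 members lower and 3 higher in MYD88_L265P than in IKK_K171E (14 and 4 adjusted over the list alone), with the lymphotoxin genes Ltb (-1.38) and Lta (-1.25) beside Ccl22. The camera adjusted p was 0.0101 (adjusted p = 0.404 with an estimated correlation), and the call ended without IKK_K171E replicate 1 (0.0969). The cytokine list had 10 of 42 lower and 3 higher (17 and 5 adjusted over the list alone), with Cxcl10 at -1.37 (camera adjusted p = 2.57e-04, adjusted p = 0.312 with an estimated correlation). Of the B cell activation list 7 of 27 fell and 0 rose (15 and 2 adjusted over the list alone), with Slamf1 at -1.44 and Fas at -1.34 beside Fcer2a (camera adjusted p = 2.54e-06, adjusted p = 0.312 with an estimated correlation). H2-Oa (-0.89) was the 1 of 16 MHC class II genes called, with 8 lower adjusted over the list alone (camera adjusted p = 3.08e-04, adjusted p = 0.381 with an estimated correlation). The interferon list had 0 of 29 members called, also 0 adjusted over the list alone, and a median of -0.30 (camera adjusted p = 0.0277, adjusted p = 0.689 with an estimated correlation), a call that ended without IKK_K171E replicate 1 (0.843) and without MYD88_L265P replicate 2 (0.969, median -0.070). The interferon median was -0.50 without IKK_K171E replicate 2 and -0.57 without MYD88_L265P replicate 1.

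All of these groups moved beside the markers of other cell types, of which 5 lists were lower in MYD88_L265P than in IKK_K171E. Monocytes and macrophages had a median of -0.48 (-0.31 without IKK_K171E replicate 1), with 1 of 20 lower (Ccr2 -0.87) and 9 adjusted over the list alone (camera adjusted p = 2.84e-06, adjusted p = 0.368 with an estimated correlation). Dendritic cells had 4 of 15 lower and 1 higher (6 and 1 adjusted over the list alone), with Clec10a at -0.79 and Itgax at -0.69 beside Flt3 (camera adjusted p = 0.00542, adjusted p = 0.312 with an estimated correlation). T cells had 2 of 19 lower (14 adjusted over the list alone), Cd3g at -1.14 and Cd3e at -0.61 (camera adjusted p = 6.33e-07, adjusted p = 0.312 with an estimated correlation). NK cells had 2 of 14 lower and 1 higher (8 and 1 adjusted over the list alone), the signalling chain gene Tyrobp at -1.05 and Nkg7 at -0.75 (camera adjusted p = 0.00118, adjusted p = 0.404 with an estimated correlation). Neutrophils had 2 of 18 lower (5 adjusted over the list alone), Cxcr2 at -0.85 and S100a8 at -0.52 (camera adjusted p = 1.65e-04, adjusted p = 0.312 with an estimated correlation), a call that ended with the features of lowest signal left out (0.0513).

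Among lists that camera did not call between the 2 constructs, mature B cell identity genes had 3 higher and 5 lower of 28, STAT3 genes 3 and 1 of 24, migration genes 1 and 2 of 24 with Ccr9 at 1.70, and survival genes 2 and 1 of 11 with Pim2 at 1.78. Jun was the 1 of 30 MAPK feedback genes called (0.63), Tirap, an adaptor that recruits MYD88, the 1 of 30 Toll-like receptor genes (0.82), and Cr2 (-1.33) 1 of 2 called among 17 marginal zone genes. Germinal centre genes had 1 higher and 1 lower of 19, Fas was the 1 called of 18 apoptosis and of 22 p53 genes, and 0 members passed in the MHC class I, glycolysis, B cell receptor, FOXO and erythroid lists. MHC class I passed as lower without IKK_K171E replicate 2 (camera adjusted p = 0.0153), without MYD88_L265P replicate 1 (0.0432), under quantile normalization (5.08e-04), with a common median (0.0312) and with the features of lowest signal left out (0.0210). Quantile normalization also called mature B cell identity (8.79e-04) and B cell receptor genes (0.00599) as lower. Without IKK_K171E replicate 1, glycolysis passed as higher (0.00420) and the MAPK feedback list as lower (0.0424). The count of 377 became 592 without either EV array, 42 and 14 without IKK_K171E replicates 1 and 2, and 87 and 33 without MYD88_L265P replicates 1 and 2. A common median moved the share of higher calls from 49.9% to 66.2%.

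The responses to the 2 constructs were set against each other last. Of the 206 features higher in IKK_K171E than in EV, 131 were also higher in MYD88_L265P, among them Ccne2, E2f3, Idi1, Rrs1 and Nop58. In the direct comparison 57 of the 206 were lower in MYD88_L265P than in IKK_K171E, among them Ccl22, Cxcl10, Lcp2 and Clec10a. Of the 89 features lower in IKK_K171E, 78 were also lower in MYD88_L265P, among them Txnip, Adgre1 and Cd22. Cd96, Fas and Flt3 were the 3 features called in opposite directions, higher in IKK_K171E (1.04, 0.58 and 0.75) and lower in MYD88_L265P (-0.73, -0.76 and -0.88). MYD88_L265P alone stood above both other groups in 175 features and below both in 102, and IKK_K171E stood above both in 57 and below both in 2. Independent lists would share 19.2 higher and 6.52 lower features, a number that does not allow for the shared EV arrays. Log2 fold changes of the 2 comparisons correlated across genes, which are not independent replicates, at 0.709 (0.482 to 0.522 in 100 simulated data sets with no effect and shared controls), with a covariance of 0.0663 (simulated mean 0.00800). The simulated noise was independent between genes, while the estimated correlation between genes was 0.972 in the G2/M list and 0.706 in the G1/S list. The simulated range is therefore too narrow to show that the observed value exceeds what shared controls give. The 2 EV arrays cannot be split into separate sets for the 2 comparisons with replicates in each, so part of the overlap may come from the shared controls. Higher and lower shared features numbered 0 and 0 without IKK_K171E replicate 1, where limma called no feature in IKK_K171E over EV, 52 and 36 without EV replicate 2, 12 and 7 without MYD88_L265P replicate 1, and 10 and 6 without MYD88_L265P replicate 2. The higher count was 338 without EV replicate 1 and 357 without IKK_K171E replicate 2.

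**Figure D3:**
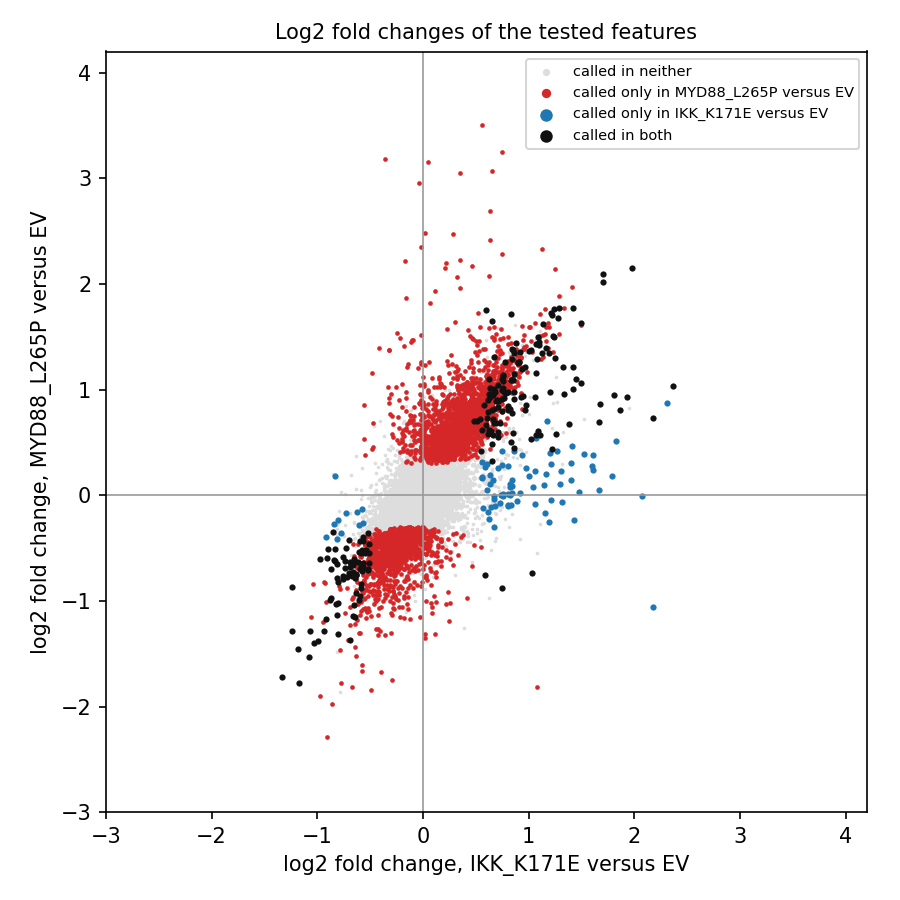
Log2 fold change over EV of each of the 21542 tested features in IKK_K171E (horizontal axis) and MYD88_L265P (vertical axis). Each point is 1 feature, coloured by the comparison in which limma called it, and 131 features were higher and 78 lower in both.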

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

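The features outside the comparisons of named genes were read from a planned fit of all features. In that fit, 3201 features carried no gene symbol or several, and limma called 172 of them higher and 155 lower in MYD88_L265P than in EV. Of the 172, 78 had no gene listed at all, and the largest log2 fold change was 4.04. In IKK_K171E against EV, 11 of these features were higher and 1 lower, 5 of the 11 had no gene listed, and the largest log2 fold change was 1.97. Because they could not be assigned to 1 gene, none of these features entered the counts or lists of named genes. Their identity was not examined.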

How the results depend on the processing

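Quantile normalization and the common median were applied to the gene lists only after the results were seen, while the tests on named genes and counts were planned. No called feature changed sign in any alternative, and no named gene reversed. For most alternatives this was fixed in advance. The arrays of the 2 groups were separated in every called feature, so leaving out 1 array cannot change its sign. Variance models, array weights and thresholds leave the log2 fold changes as they are. Variance models with trend or robust moderation kept every count of features within 1.5 times.

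Leaving out 1 array assumes that the lone array varies like the other groups. Counts in MYD88_L265P over EV then ran from 142 to 2124 higher and from 49 to 1430 lower, in IKK_K171E over EV from 0 to 418 higher and from 0 to 95 lower, and in MYD88_L265P over IKK_K171E from 8 to 307 higher and from 6 to 285 lower. Shared features ran from 0 to 357 higher and from 0 to 84 lower, and the correlation of the 2 sets of log2 fold changes from 0.535 (without IKK_K171E replicate 1) to 0.788. The lowest counts came without MYD88_L265P replicate 2 (142 and 49), without IKK_K171E replicate 1 (0 and 0, with limma, where 2355 had an unadjusted p under 0.05) and without IKK_K171E replicate 2 (8 and 6). Fewer arrays lower the power by construction. Where a count rose, the cause was not tested.

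With the replicate block of the descriptions, IKK_K171E over EV had 462 higher and 164 lower features, and 349 and 129 were shared. With the title numbers as a replicate block, where EV replicate 1 has no partner and drops out, 998 features were lower in MYD88_L265P than in EV, 488 were higher in IKK_K171E than in EV, 699 and 552 differed between the constructs, and 402 were shared as higher. Deviations from group means of same-numbered arrays correlated across genes at 0.211 (EV and IKK_K171E), 0.105 (EV and MYD88_L265P) and 0.144 (IKK_K171E and MYD88_L265P). With 2 numbers per group both pairs of a comparison give the same correlation, and no label names a shared culture or day, so the unpaired fit was kept. In IKK_K171E over EV the title numbers ended the calls of the B cell activation (adjusted p = 0.126), stress response (median -0.0039, 0.477) and T cell lists (0.703), and the description numbers added the interferon (0.00477) and glycolysis lists (0.0438). In MYD88_L265P over EV the B cell activation list was added as lower by the description (0.0443) and title numbers (0.00109) and the interferon list by the title numbers (0.0263), which also added mature B cell identity as lower in MYD88_L265P than in IKK_K171E (0.0411).

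The common median left 753 features lower in MYD88_L265P than in EV. It subtracts the array medians, which were lowest in MYD88_L265P. For IKK_K171E over EV, quantile normalization gave 135 lower, array weights 99 higher and 24 lower, the filter on low signal 142 lower, and a fit that included features without a single gene symbol 103 and 28. Shared features were 64 and 23 with array weights and 57 and 25 with all features. The cause was not tested. Only the 2 groups compared gave 44 and 7 in IKK_K171E over EV, and 307 and 285 in MYD88_L265P over IKK_K171E. These fits replace the spread of the group left out. A 2-fold threshold left 387 and 91, 80 and 8, and 65 and 53 in the 3 comparisons, and 31 and 7 shared, by construction.

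With an estimated correlation camera called 0 lists higher and 0 lower in each comparison, where 1, 4 and 3 lists had an unadjusted p under 0.05 and fry called 15, 4 and 14. Fry called 10 lists lower in MYD88_L265P than in EV, 1 higher and 3 lower in IKK_K171E than in EV, and 2 higher in MYD88_L265P than in IKK_K171E. Of the lists called by camera it kept 8, 4 and 10. The 4 kept in IKK_K171E over EV were the mature B cell identity, FOXO, migration and dendritic cell lists. The set tests ask different questions or allow for more correlation. Directions reversed in 3 cases. The Toll-like receptor list had a median of -0.082 in MYD88_L265P over EV and was called lower by fry (adjusted p = 0.0302). The G2/M list had a median of -0.17 in IKK_K171E over EV without EV replicate 2, and over all arrays left out in turn it ran from -0.17 to 0.92. The interferon list had a median of -0.070 in MYD88_L265P over IKK_K171E without MYD88_L265P replicate 2, where camera pointed up, and ran from -0.57 to -0.070. The cause was not tested. Signal over background was not available, so features near the floor were not separated.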

Other observations

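The gene groups of the first paragraph, and all tests of explanations except those of macrophages in the sort and of general precision, were chosen only after the results were seen. In MYD88_L265P over EV, 10 of 18 cytosolic aminoacyl-tRNA synthetase genes, which charge tRNAs, were higher and 0 lower (Tars 1.22, Hars 0.99, Lars 0.86). Camera over the 7 groups so chosen gave adjusted p = 2.84e-07 (adjusted p = 0.272 with an estimated correlation). The groups were picked from the same arrays, so the camera p-values of this paragraph are no separate evidence. Of 16 mitochondrial synthetases, 2 were higher (adjusted p = 0.0829). Serine, glycine and 1-carbon enzymes had 8 of 11 higher and 0 lower, with Shmt2 at 1.60, Psat1 at 1.53 and Mthfd1 at 1.22 (adjusted p = 2.91e-07, adjusted p = 0.272 with an estimated correlation). Slc7 amino acid transporters had 5 of 15 higher, Slc7a3 at 2.42 and Slc7a5 at 1.49 among them, around a median of -0.06 (adjusted p = 0.0458, adjusted p = 0.272 with an estimated correlation). Of 14 COPII coat and translocon genes, 6 were higher and 1 lower, with Sec24d at 1.82 and Sec31b at -0.36 (adjusted p = 2.63e-04, adjusted p = 0.272 with an estimated correlation). Guanylate-binding protein genes, which interferon induces, had 7 of 8 lower, with Gbp8 at -1.35, Gbp9 at -1.17 and Gbp5 at -1.02 (adjusted p = 6.11e-04, adjusted p = 0.272 with an estimated correlation). In IKK_K171E over EV, 6 of 11 Clec4 lectin genes were higher and 0 lower, with Clec4a3 at 2.37, Clec4a1 at 1.81 and Clec4e at 1.31 (adjusted p = 6.82e-09, adjusted p = 0.0537 with an estimated correlation). They moved beside the monocyte and macrophage list (median 0.56). The same group was higher in MYD88_L265P over EV, with 3 of 11 called (adjusted p = 0.0107, adjusted p = 0.272 with an estimated correlation).

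Monocyte and macrophage genes lay higher in IKK_K171E than in EV, with a median log2 fold change of 0.56 and 16 of 20 members above 0. The form of a lower share of B cells that was tested is one that raises all other cell types alike. The pooled T cell, neutrophil and erythroid lists had a median of 0.03 over 47 genes. The two-sided permutation p of 1e-05, the smallest that 100000 resamples can give, and of 1.2e-04 against all 5 other lists pooled (median 0.06, 76 genes), argued only against all types rising alike, although genes are not independent. Cell types absent from the sort could not rise, so a lower share of B cells as such stays open. Against the monocyte list, the permutation p was 0.13 for NK cells (median 0.24, 14 genes) and 0.16 for dendritic cells (median 0.06, 15 genes). For erythroid cells it was 0.064 (median 0.05, 10 genes). For T cells (median 0.06, 19 genes) and neutrophils (median 0.02, 18 genes) it was 3.5e-04 and 6.2e-04. Dendritic and T cell medians were alike, so a p above 0.05 in these short lists does not show a level like that of monocytes. Camera called the NK cell, dendritic cell and T cell lists higher as well, so a joint rise of some cell types stays open. The T cell list had 0 of 19 members called, and its call ended with the features of lowest signal left out. Macrophages that passed the EGFP sort stayed open. The 5 brightest members had a median of 0.47, with Lyz2 at 1.41 (limma adjusted p = 0.0501), Cd68 at 0.77, Ctsd at 0.47, Mpeg1 at -0.09 and Adgre1 at -1.17. The bootstrap interval of this median, -1.17 to 1.41, spans the lowest to the highest member. With 5 values it always does, so it cannot decide the question. Of the 20 genes 8 lay above the median feature of EV and 2 are in another list, so that induction in B cells by the construct, which was not tested, may also account for the pattern.

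Mitotic genes had a median of 0.86 in MYD88_L265P over EV (1.42 without EV replicate 1, 0.31 without EV replicate 2) with few calls. Replicate 1 minus replicate 2 was 1.13 in EV and 0.31 in IKK_K171E, each positive in 39 of 39 members, and -0.090 in MYD88_L265P. The bootstrap 95% interval of the last (-0.12 to -0.05) is over genes, whose estimated correlation was 0.972, and not over replicates. It cannot decide whether a difference followed the replicate number in all 3 groups. A difference shared by EV and IKK_K171E stays open, and a replicate block by the description numbers raised the called members from 2 to 16. The title numbers leave EV replicate 1 without a partner. A fit with them cannot separate the block from the loss of that array. The median residual SD of the list was 0.490 against 0.116 in random lists of matched intensity (95th percentile 0.139), so other genes of like intensity did not share this spread. A large median with few calls already implies a wide spread in the list. The excess is therefore no separate evidence on its cause. A difference in cycling between the EV cultures stays open as a candidate explanation, as does an effect of MYD88_L265P.

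The 2 IKK_K171E arrays differed along the response to MYD88_L265P, with a correlation across genes of 0.506 between replicate 1 minus replicate 2 and MYD88_L265P minus EV. Replicate 1 minus replicate 2 of EV correlated with MYD88_L265P minus IKK_K171E at 0.223 and with MYD88_L265P minus EV at 0.289. Ikbkb was higher by 0.67 in IKK_K171E replicate 1 and differed by -0.25 in EV. The numbering sets the sign of each difference and no further arrays give a no-change value, so the level of the transduced gene and a difference between cultures that also touched EV cannot be told apart.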
